A study of Homo sapiens with 12 samples.

How the data were processed

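Poly(A) RNA was sequenced in 12 libraries: UWB1.289 and UWB1.289+BRCA1 cells, each in control medium, with 1000 µM CT913 or with 40 µM CT913-M1 for 24 h, in 2 libraries per group. Per the labels' protocols, cells grew in T-75 flasks, UWB1.289+BRCA1 medium also held G-418, RNA was extracted with a column kit including DNase digestion, and stranded mRNA libraries were read as pairs of 75 bases on a NextSeq500. The labels give the replicates no numbers and do not say whether they came from separate cultures. Replicate numbers here only name libraries, nothing was paired, and p-values measure only the spread between these libraries, which may be technical.

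The authors deposited whole-number counts per Ensembl gene, not normalized. Per the submitters' processing notes, bcl2fastq, Trimmomatic 0.36, STAR 2.5.1, featureCounts, DESeq2 1.10.1 and DESeq were used, and GRCh38.p7 and hs37d5 were named as builds, without the role of each. The strand setting of the counting and the annotation release are not given in the sources used here, so genes that overlap others or have antisense partners are uncertain. Genes with near-identical copies (HSPA1A and HSPA1B, metallothioneins, AKR1C1 and AKR1C2, histones) may share reads and are uncertain too. The deposited table also held, per the file headers, the sum of the counts over all libraries, a score column with their standard deviation and the percent of the total count, which the authors made from the counts and which entered no test. The table listed 57952 genes, of which 30909 had a count above 0 and 52338 had an identifier in GENCODE 29 on GRCh38. Coordinates are those of GENCODE 29 and were not converted. The 13 genes encoded in mitochondrial DNA were at 0 in every library, so this list was not used to judge RNA quality.

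Library totals ran from 7336579 to 16944819 counts, and 97.3 to 97.6% of counts were in protein-coding genes. Replicates correlated at r = 0.990 to 0.993 on the log2 CPM scale and differed by more than sampling noise in every group (chi-square per degree of freedom 1.24 to 5.91 over genes with at least 40 counts). Sampling noise alone in 1 library sequenced again would not give this. Differences between sequencing runs were not measured, and separate preparations of 1 culture are not excluded. In R 4.3.3 with edgeR 4.0.16, genes were filtered by filterByExpr, which left 15784, libraries were scaled by TMM, and 1 model with a mean per group was fitted to all 12 libraries. Its common dispersion was 0.00273 (a coefficient of variation of 5.22%), with 6 residual and 14.7 prior degrees of freedom. The 9 comparisons were each compound against control in each line, CT913-M1 against CT913 in each line, the lines in control, and the difference between lines of each compound's effect. Each used edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes used a prior count of 0.125, and a gene at 0 in a whole group has a lower bound from 3 counts per library instead. Groups of 2 allow neither a test for outlying libraries nor a count of other splits of the libraries.

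The design, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. Named are BRCA1; the 6 largest rises and 6 largest falls in each comparison with control among called protein-coding genes with a mean of at least 100 counts in the higher group; 3 members of lowest p, called in the list direction, of each called list, or of the 6 lists of lowest p where fewer were called; MGMT, CDKN1A, MDM2, GDF15, ATF3, DDIT3, HMOX1, CYP1A1 and CCNB1 in any case; 5 and 5 genes between compounds; 8 and 8 between lines; and the 5 of lowest p in each direction for each difference between lines. Some genes that the rule names are not reported here, and no other gene took their place. Of 795 list entries 787 matched the table. The 35 lists were p53 targets, homologous recombination, Fanconi anemia, mismatch repair, base excision and direct reversal, replication, mitosis, ATF4 targets, the unfolded protein response, NRF2, heat shock, AhR and xenobiotic response, cholesterol synthesis, lipid synthesis, PPAR and fatty acid oxidation, hypoxia and glycolysis, NF-kB, interferon, immediate early and AP-1, apoptosis, metallothioneins, autophagy, replication-dependent histones, mitochondrially encoded genes, ribosomal proteins, ribosome biogenesis, YAP and TEAD, TGF-beta, epithelial, mesenchymal, ovarian lineage and keratin genes, and markers of fibroblasts, of blood and immune cells and of endothelium. Lists with at least 5 measured genes, 31 in number, were tested by camera in limma 3.58.1 with the correlation between genes estimated for each list. Estimates from 6 residual degrees of freedom are uncertain. All 43 list calls also held with the preset correlation of 0.01 and by fry. Fry tests whether a list's genes move one way without comparing them with other genes. Both settings called more lists in every comparison, so that these calls held was nearly ensured and is weak support.

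The steps were tested on simulated counts drawn with the means and sizes of these libraries. For CT913 against control in UWB1.289, over 15100 genes, edgeR recovered 46.2% of 65 genes changed by 0.5 on the log2 scale. It recovered 80.3% of 66 genes at 1 and 93.9% of 66 at 2, with 10 false calls. For the difference between lines with CT913 the shares were 24.6%, 69.7% and 84.8%, with 8 false calls. Far fewer genes were changed there than passed in the real comparisons, so these shares and false calls need not hold for them. A list of 25 genes raised by 1 was found, and 0 of 30 unchanged lists were called. The correlation and covariance of changes with shared controls were set against 50 simulated data sets of unchanged groups.

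Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of the compared groups alone and leaving out each library, which leaves a group with 1 library assumed to vary like the others. For lists they were the preset correlation, fry, RLE and, added after the data were seen, leaving out each library, and for correlations RLE, genes of at least 10 CPM, leaving out each library and, added after the data were seen, a different control library for each compound. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.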

Results

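Gene expression was measured in UWB1.289, an ovarian cancer cell line that lacks functional BRCA1, and in UWB1.289+BRCA1, the derived line with BRCA1 added back. BRCA1 is a core factor of DNA repair by homologous recombination. Both lines were kept for 24 h in medium alone (control), in medium with 1000 µM CT913, a triazene compound, or with 40 µM CT913-M1, its metabolite. Each of the 6 groups held 2 libraries, 12 in all, so that n = 2 per group throughout. Total counts in UWB1.289 were 10047134 and 9272205 in control, 10603980 and 7336579 with CT913, and 14017312 and 7722650 with CT913-M1. In UWB1.289+BRCA1 they were 9471000 and 8032683 in control, 9418459 and 7689605 with CT913, and 8071135 and 16944819 with CT913-M1. The first principal component (42.7% of the variance) parted the cell lines, the second (27.1%) parted CT913 from the other libraries, and the third (14.6%) parted CT913-M1 from control in each line. Unless stated otherwise, changes are log2 fold changes ± SE from edgeR's quasi-likelihood test, genes are said to have risen or fallen at an adjusted p under 0.05, and levels are CPM (counts scaled to library size by TMM) ± SD. In the 198 named results between groups that passed, both libraries of a group lay beyond both of the other (33.3% by chance for unselected genes), which their selection as called genes nearly ensures.

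The BRCA1 transcript itself was examined first, since it separates the lines by design. BRCA1 (ENSG00000012048, chromosome 17, 43044295 to 43170245, minus strand, GENCODE 29 on GRCh38) stood at 26.0 ± 0.0532 CPM in UWB1.289 control and at 122 ± 6.88 CPM in UWB1.289+BRCA1 control, a 4.71-fold difference (log2 2.24 ± 0.09). With CT913 it rose 6.43-fold in UWB1.289+BRCA1, to 786 ± 51.4 CPM (log2 2.69 ± 0.07), with 822.7 and 750.1 CPM in the libraries. In UWB1.289 it stood at 23.9 ± 1.3 CPM with CT913 (log2 -0.11, 95% interval -0.33 to 0.11, adjusted p = 0.382 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CT913-M1 lowered BRCA1 in UWB1.289+BRCA1 to 94.2 ± 6.75 CPM (log2 -0.38 ± 0.07), and in UWB1.289 the level was 23.3 ± 1.3 CPM (log2 -0.15 ± 0.10, adjusted p = 0.294 by the same edgeR test). The change with CT913 differed between the lines by 2.80 ± 0.13, whereas the difference for CT913-M1, -0.24 ± 0.13, did not pass the test (adjusted p = 0.201 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). NBR2 (ENSG00000198496, 43125610 to 43153671, plus strand), which starts from the same promoter region in the other direction, changed by -0.16 ± 0.22 with CT913 in UWB1.289+BRCA1 and rose by 0.70 ± 0.17 in UWB1.289. NBR2 lies inside the annotated span of BRCA1 on the other strand, and the strand setting of the counting is not given in the sources used here, so its counts are uncertain. The counts do not tell the added BRCA1 copy from the cell's own.

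**Figure D1:**
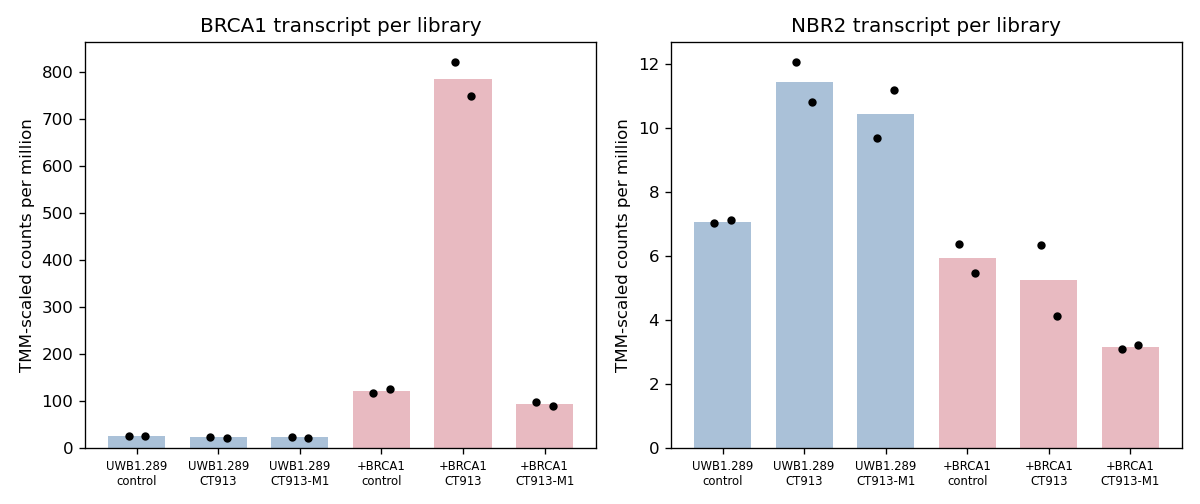
CPM, scaled by TMM factors, of BRCA1 (left) and of NBR2 (right) in the 12 libraries. Points are single libraries and bars the mean of 2; BRCA1 lies at 822.7 and 750.1 with CT913 in UWB1.289+BRCA1 and at or under 127.3 in the 10 other libraries.

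The effect of CT913 in cells without functional BRCA1 was asked first in UWB1.289. CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 22.4-fold, from 2.46 ± 0.877 to 54.8 ± 1.1 CPM. It was followed by FAM46C (log2 3.66 ± 0.31), the acid sphingomyelinase gene SMPD1 (3.16 ± 0.24), ANGPTL4, an inhibitor of lipoprotein lipase (3.14 ± 0.13), CLU, a secreted chaperone (2.84 ± 0.16), and OSGIN1 (2.83 ± 0.22). The largest falls were in CA2, a carbonic anhydrase (-3.78 ± 0.14), the cadherin gene CDH6 (-3.32 ± 0.08), CCDC146 (-3.10 ± 0.13), the interferon-induced IFI44L (-2.97 ± 0.26), the transcription factor gene SOX2 (-2.92 ± 0.21) and CCBE1 (-2.83 ± 0.26). In all, 8477 of 15784 genes passed the test, 4253 higher and 4224 lower, and 1169 and 920 of these by at least 2-fold.

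Among the fixed lists, ribosome biogenesis fell together with CT913 in UWB1.289, with 28 of 30 genes lower and none higher (median -0.80), among them NCL (-1.32 ± 0.06), UTP20 (-1.57 ± 0.07) and NOP56 (-1.18 ± 0.06). DNA replication genes fell in 34 of 36 cases (median -0.79), with CDC6 at -1.14 ± 0.08, the helicase subunit gene MCM3 at -1.05 ± 0.08 and RFC3 at -0.94 ± 0.07. Mitotic genes fell in 34 of 38 cases and rose in 1 (median -0.55), with TPX2 at -0.87 ± 0.06, PRC1 at -0.84 ± 0.06 and CDK1 at -0.91 ± 0.06. Genes of the NRF2 response to oxidants rose in 15 of 23 cases and fell in 3 (median 0.72), led by SRXN1 (1.77 ± 0.08) and TXNRD1 (1.11 ± 0.07). The p53 target list had 16 of 28 genes higher and 2 lower (median 0.68), with CDKN1A, GDF15 (2.72 ± 0.20) and the death receptor gene TNFRSF10B (1.03 ± 0.08). Autophagy and lysosome genes rose in 17 of 29 cases and fell in 1 (median 0.33), with WIPI1 at 1.5 ± 0.10, GABARAPL1 at 1.62 ± 0.11 and SQSTM1, a member of the NRF2 list too, at 0.95 ± 0.07. Adjusted over the list alone, 28, 34 and 34 genes of the first 3 lists fell, and 16, 16 and 18 of the others rose. By camera with an estimated correlation these 6 lists passed at adjusted p = 0.0321 (ribosome biogenesis), 0.0335 (replication and NRF2), 0.0392 (mitosis and p53 targets) and 0.0492 (autophagy). With either control library left out 1 list passed, with either CT913 library left out 0, and RLE scaling ended the call of autophagy.

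CT913 was compared with control in the same way in UWB1.289+BRCA1. PDK4, a kinase that restrains pyruvate oxidation, rose 29.4-fold (log2 4.88 ± 0.27), ANGPTL4 21.9-fold (4.45 ± 0.15), the pentraxin gene PTX3 20.9-fold (4.39 ± 0.19) and TLR2, a receptor of innate immunity, 18.2-fold (4.19 ± 0.19). CDKN1A rose 15-fold, from 4.43 ± 0.51 to 66.5 ± 7.67 CPM (log2 3.91 ± 0.16), and BIRC3, an inhibitor of apoptosis induced by NF-kB, 12.3-fold (3.62 ± 0.14). PTX3 and TLR2 rose from 1.84 and 1.93 CPM in control to 39.6 and 35.6 CPM. These levels lay under the 136 and 50.4 CPM of UWB1.289 with CT913. PDK4, ANGPTL4 and CDKN1A lay higher in both libraries than in UWB1.289 with CT913, though this difference was not tested. BIRC3, at 193 and 152 CPM, overlapped UWB1.289 with CT913 (161.6 and 163 CPM). Its control level was lower in UWB1.289+BRCA1 (14 CPM) than in UWB1.289 (54.7 CPM). LIX1 fell by 5.0 ± 0.30 on the log2 scale, followed by the autophagy gene MAP1LC3C (-4.96 ± 0.27), CA2 (-4.49 ± 0.12), the cation transporter gene SLC22A3 (-4.02 ± 0.30), CCDC146 (-3.85 ± 0.10) and VTCN1 (-3.85 ± 0.21). Of 8103 genes that passed the test 3882 were higher and 4221 lower, and 1141 and 929 of these by at least 2-fold.

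With CT913 in UWB1.289+BRCA1, inflammatory targets of NF-kB rose in 20 of 25 cases and fell in 2 (median 1.45), with ICAM1 at 2.87 ± 0.08, BIRC3 as above and the NF-kB inhibitor gene NFKBIA at 1.87 ± 0.11. Immediate early and AP-1 genes rose in 22 of 27 cases and fell in 3 (median 0.94), with DUSP6 at 1.48 ± 0.08, ETV5 at 1.27 ± 0.07 and HBEGF at 2.04 ± 0.11. NRF2 genes rose in 15 of 23 cases and fell in 3 (median 0.67), with SRXN1 at 2.15 ± 0.09, TXNRD1 at 1.40 ± 0.07 and SQSTM1 at 1.21 ± 0.07. The apoptosis list, which holds inhibitors of apoptosis beside genes that promote it, had 17 of 25 genes higher and 4 lower (median 0.54). Its higher members included BIRC3 as above, TNFRSF10B at 1.11 ± 0.09 and FAS at 1.1 ± 0.09. The rise of this list therefore does not speak for or against cell death. The p53 targets rose in 14 of 28 cases and fell in 5 (median 0.20), with GADD45A at 1.49 ± 0.09. Autophagy genes rose in 14 of 29 cases and fell in 1 (median 0.29), with GABARAPL1 at 1.76 ± 0.10 and WIPI1 at 1.19 ± 0.09. Fatty acid oxidation targets of PPAR rose in 9 of 17 cases and fell in 3 (median 0.28), with PDK4, ANGPTL4 and PLIN2 (0.97 ± 0.12). Adjusted over the list alone, 20, 22, 16, 17, 14, 14 and 11 genes of these 7 lists rose.

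All 36 replication genes fell with CT913 in UWB1.289+BRCA1 (median -1.06), with MCM3 at -1.54 ± 0.08, CDC6 at -1.51 ± 0.08 and MCM4 at -1.07 ± 0.06. Ribosome biogenesis fell in 28 of 30 cases (median -0.74), with NCL at -1.04 ± 0.06, NOP56 at -1.12 ± 0.06 and NPM1 at -1.19 ± 0.07, and the mitotic list in 28 of 38, with 1 higher (median -0.46). Homologous recombination genes fell in 21 of 27 cases, and BRCA1 was the member that rose (median -0.54), with XRCC2 at -1.28 ± 0.10, RAD54L at -1.30 ± 0.10 and the nuclease gene EXO1 at -0.88 ± 0.08. Mismatch repair fell in 11 of 14 cases (median -0.51), with RFC3 at -1.06 ± 0.07. Targets of YAP and TEAD fell in 12 of 19 cases and rose in 3 (median -0.39), with F3, the tissue factor gene, at -2.18 ± 0.06, AJUBA at -1.72 ± 0.06 and CRIM1 at -1.03 ± 0.06. Adjusted over the list alone, 36, 29, 30, 21, 13 and 12 genes of these lists fell. By camera with an estimated correlation, adjusted p was 0.0186 for replication, NRF2 and ribosome biogenesis, 0.0289 for NF-kB, 0.0497 for p53 targets and 0.0495 for the other 8 lists of this comparison. Replication, NRF2, ribosome biogenesis and NF-kB passed with each of the 4 libraries left out, while the number of lists was 5 without control replicate 1 or 2, 7 without CT913 replicate 2 and 11 without CT913 replicate 1. RLE scaling ended the calls of autophagy, mismatch repair, p53, PPAR and YAP targets.

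CT913-M1 in UWB1.289 raised the lysosomal membrane gene LAMP3 8.37-fold (log2 3.06 ± 0.12), the hypoxia-responsive NDRG1 7.79-fold (2.96 ± 0.07), the stress cytokine gene GDF15 7.16-fold (2.84 ± 0.20), ANGPTL4 (2.37 ± 0.14), the transcription factor gene GATA6 (2.26 ± 0.21) and MOV10L1 (2.13 ± 0.22). The largest falls were in FGFBP1 (-2.81 ± 0.09), FAM111B (-2.45 ± 0.10), TRIM55 (-2.25 ± 0.20), SIAH3 (-2.22 ± 0.19), CCDC146 (-2.22 ± 0.11) and the protocadherin gene PCDH19 (-2.17 ± 0.08). The test passed 5359 genes, 2580 higher and 2779 lower, with 380 and 322 of them changed at least 2-fold. Without control replicate 1 the number was 3219, without CT913-M1 replicate 1 it was 3315, and DESeq2 passed 3454.

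ATF4 targets of the integrated stress response rose with CT913-M1 in UWB1.289 in 28 of 34 cases and fell in none (median 0.51), with TRIB3 at 1.84 ± 0.07, PPP1R15A at 1.81 ± 0.09 and DDIT3, which encodes CHOP, at 1.44 ± 0.08. Hypoxia and glycolysis genes rose in 17 of 28 cases and fell in 5 (median 0.29), with NDRG1, VEGFA (1.15 ± 0.07) and KDM3A (0.79 ± 0.08). Replication genes fell in 35 of 36 cases (median -0.83), with the ribonucleotide reductase gene RRM2 at -1.54 ± 0.07, MCM4 at -0.97 ± 0.06 and CCNE2 at -1.75 ± 0.12. Heat shock genes fell in 21 of 23 cases (median -0.66), with the chaperone genes HSPA8 at -1.40 ± 0.06, HSPH1 at -1.16 ± 0.06 and HSPE1 at -1.27 ± 0.07. Cholesterol synthesis genes fell in 22 of 25 cases (median -0.92), with HMGCS1 at -1.76 ± 0.07, IDI1 at -1.42 ± 0.07 and ACAT2 at -1.21 ± 0.07, and lipid synthesis genes in 10 of 15 (median -0.39), with the desaturase genes SCD at -0.81 ± 0.05, FADS1 at -0.84 ± 0.07 and FADS2 at -1.24 ± 0.11. Mitotic genes fell in 29 of 38 cases and rose in 1 (median -0.34), with MKI67 at -0.77 ± 0.06, ANLN at -0.67 ± 0.06 and KIF20A at -0.71 ± 0.07. Adjusted over the list alone, 28 and 17 genes of the first 2 lists rose, and 36, 21, 23, 10 and 30 of the others fell. Adjusted p by camera with an estimated correlation was 0.00871 for the ATF4 and replication lists, 0.0162 for heat shock, 0.0313 for mitosis, hypoxia and cholesterol, and 0.0420 for lipid synthesis. The ATF4, replication and heat shock lists passed with each of the 4 libraries left out; without CT913-M1 replicate 1 these 3 were all that passed, without CT913-M1 replicate 2 there were 4, without control replicate 2 lipid synthesis no longer passed, and RLE scaling ended the calls of hypoxia and lipid synthesis.

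CT913-M1 in UWB1.289+BRCA1 raised PTX3 18.4-fold (log2 4.2 ± 0.19), ANGPTL4 14.1-fold (3.82 ± 0.15), the lymphotoxin gene LTB 8.94-fold (3.16 ± 0.28), OSGIN1 8.79-fold (3.14 ± 0.26), GDF15 7.56-fold (2.92 ± 0.14) and the cytokine gene IL6 7.29-fold (2.87 ± 0.21). PTX3 rose from 1.84 to 35.3 CPM, under the 51.9 CPM of UWB1.289 control and the 132 CPM of UWB1.289 with CT913-M1. The other genes named here as rising reached higher levels than in UWB1.289 with CT913-M1. MAP1LC3C fell (-3.69 ± 0.22), as did PPARGC1A, a coactivator of mitochondrial biogenesis (-2.96 ± 0.20), CLIC5 (-2.72 ± 0.24), RCAN2 (-2.67 ± 0.15), CILP (-2.60 ± 0.24) and ADAMTS15 (-2.55 ± 0.11). In this line 8009 genes passed the test, 3733 higher and 4276 lower, with 1159 and 775 changed at least 2-fold. Without a filter on low counts the higher share of the called genes was 58.4% instead of 46.6%.

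Immediate early and AP-1 genes rose with CT913-M1 in UWB1.289+BRCA1 in 24 of 27 cases and fell in none (median 1.06), with the phosphatase gene DUSP5 at 1.99 ± 0.07, MYC at 1.65 ± 0.08 and ATF3 at 2.47 ± 0.14. NF-kB targets rose in 20 of 25 cases and fell in none (median 1.15), with the chemokine gene IL8 at 1.53 ± 0.08, ICAM1 at 1.22 ± 0.08 and IL6. PTPRC, a marker of blood cells, stood at 13.1 and 6.55 CPM before TMM scaling in these libraries and at 3.21 to 7.12 CPM in the 10 others. NRF2 genes rose in 16 of 23 cases and fell in 2 (median 0.67), with SQSTM1 at 1.07 ± 0.07, OSGIN1 and SRXN1 (0.98 ± 0.09). Hypoxia and glycolysis genes rose in 18 of 28 cases and fell in 3 (median 0.38), with NDRG1 at 2.30 ± 0.06, PFKP at 1.15 ± 0.08 and ADM at 2.23 ± 0.20. ATF4 targets rose in 23 of 34 cases and fell in 3 (median 0.44), with TRIB3 at 1.60 ± 0.07, PPP1R15A at 2.04 ± 0.09 and DDIT4 at 1.2 ± 0.06. Adjusted over the list alone, 26, 20, 16, 18 and 25 genes of these lists rose. Camera with an estimated correlation gave adjusted p = 0.0192 for the first 4 lists and 0.0267 for ATF4 targets, and all 5 passed with each of the 4 libraries left out. Replication genes fell in 25 of 36 cases and rose in 3 (median -0.53, 26 lower adjusted over the list alone), with CCNE2 at -1.53 ± 0.12, POLA1 at -1.41 ± 0.11 and RRM2 at -0.82 ± 0.07, but the list did not pass (adjusted p = 0.0997 by camera with an estimated correlation).

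**Figure D2:**
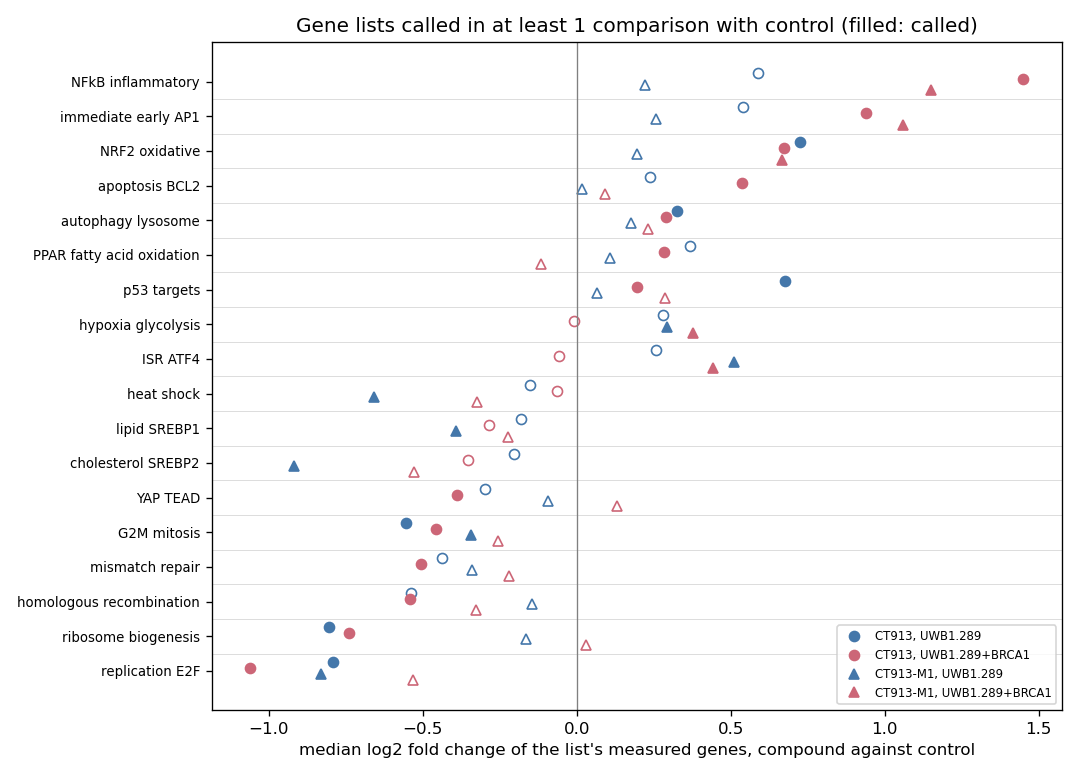
Median log2 fold change against control of the measured genes of each list (horizontal axis) in the 4 comparisons of a compound with control, 2 libraries per group. Filled symbols passed camera at an adjusted p under 0.05; the NF-kB list lies at 1.45 and 1.15 in UWB1.289+BRCA1, and replication at or under -0.53 in all 4.

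Genes fixed in advance for stress, repair and cycle were read in the same 4 comparisons. ATF3 rose by 2.10 ± 0.13 with CT913 and 1.38 ± 0.14 with CT913-M1 in UWB1.289, and by 2.21 ± 0.14 and 2.47 ± 0.14 in UWB1.289+BRCA1. GDF15 rose 2.45-fold with CT913 in UWB1.289+BRCA1, beside a log2 change of 2.72 in UWB1.289. CDKN1A rose with CT913-M1 by 1.64 ± 0.24 in UWB1.289 and 0.90 ± 0.22 in UWB1.289+BRCA1, and the latter call ended without CT913-M1 replicate 2, at 0.70. MDM2, like CDKN1A a target of p53, lay between -0.07 ± 0.08 and 0.11 ± 0.08 in the 4 comparisons and passed the test in none, with a value of -0.01 for CT913-M1 in UWB1.289+BRCA1 that changed sign with RLE scaling (0.00361). HMOX1, the heme oxygenase gene, rose by 1.73 ± 0.22 and 1.91 ± 0.24 with CT913 in UWB1.289 and UWB1.289+BRCA1 and by 0.89 ± 0.24 and 1.15 ± 0.25 with CT913-M1, where the call in UWB1.289 ended with DESeq2 (0.90) and without control replicate 2 (0.70). MGMT, which reverses alkylation of guanine, fell by 0.80 ± 0.20 with CT913 and rose by 0.82 ± 0.16 with CT913-M1 in UWB1.289+BRCA1, and its changes in UWB1.289 were -0.20 ± 0.18 and 0.22 ± 0.17, not past the test. DDIT3 rose by 0.89 ± 0.08 and 0.31 ± 0.07 with CT913 in UWB1.289 and UWB1.289+BRCA1, and by 0.74 ± 0.07 with CT913-M1 in the latter. CCNB1 fell in all 4 comparisons, with changes of -0.90 ± 0.06 and -0.61 ± 0.06 with CT913 and of -0.52 ± 0.06 and -0.36 ± 0.06 with CT913-M1. CYP1A1 had 3 counts in all 12 libraries together and was not tested.

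**Figure D3:**
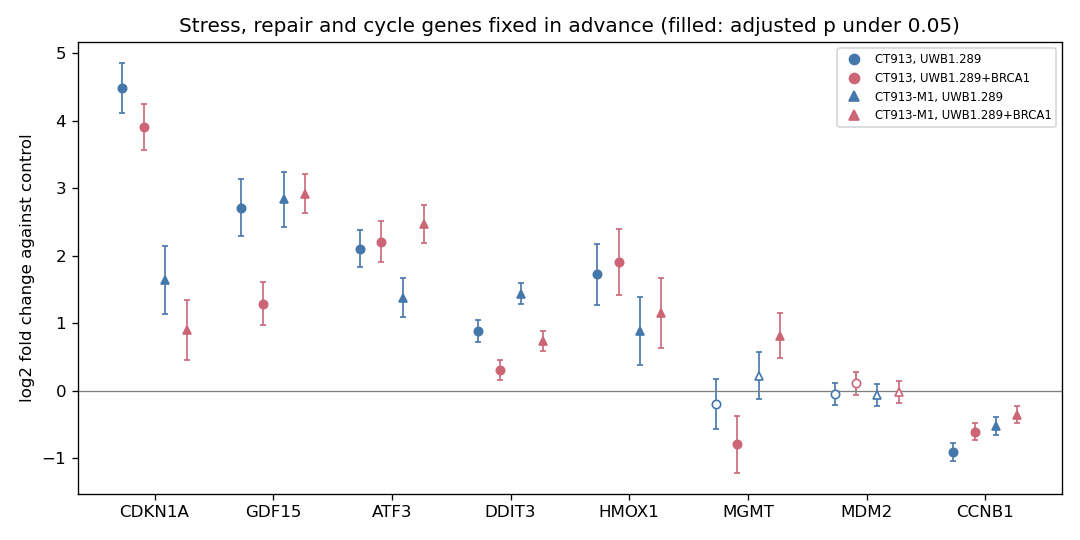
Log2 fold change against control with 95% intervals for 8 genes fixed in advance, by compound and cell line, 2 libraries per group. Filled symbols have an adjusted p under 0.05; CDKN1A reaches 4.49 with CT913 in UWB1.289, while MDM2 passes in no comparison and its value of -0.01 with CT913-M1 in UWB1.289+BRCA1 changes sign with RLE scaling.

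The parent compound and its metabolite were then compared directly, at different doses (1000 and 40 µM) and the same time. In UWB1.289, INHBA, which encodes an activin subunit, was 12.2-fold higher with CT913-M1 than with CT913 (log2 3.61 ± 0.19), and so were the interferon-induced IFI44L (3.19 ± 0.25) and EPSTI1 (2.63 ± 0.14), EDAR (3.14 ± 0.28) and NTM (2.58 ± 0.16). Lower with CT913-M1 were FAM46C (-3.21 ± 0.28), the immediate early genes EGR1 (-2.92 ± 0.24) and FOS (-2.92 ± 0.23) and CDKN1A (-2.85 ± 0.14). Ribosome biogenesis was higher with CT913-M1 in 29 of 30 cases (29 adjusted over the list alone, median 0.67, adjusted p = 0.0329 by camera with an estimated correlation). GDF15 differed by 0.12 ± 0.14, MDM2 by -0.02 ± 0.08 and BRCA1 by -0.03 ± 0.10, none past the test. The sign changed without CT913 replicate 1 for BRCA1 (0.03) and GDF15 (-0.01), without CT913-M1 replicate 2 for BRCA1 (0.01), and without CT913 replicate 2 or CT913-M1 replicate 1 for MDM2 (0.00847 and 0.00694). ATF3 (-0.72 ± 0.11) and HMOX1 (-0.84 ± 0.19) were lower, DDIT3 (0.55 ± 0.07) and CCNB1 (0.38 ± 0.06) higher, and MGMT was higher by 0.42 ± 0.17, a call that ended with DESeq2 (0.41), without CT913 replicate 1 (0.23) and without CT913-M1 replicate 1 (0.26). Of 7320 genes that passed, 3675 were higher and 3645 lower with CT913-M1. The ribosome biogenesis call ended without CT913 replicate 1 or 2 and without CT913-M1 replicate 1 (0 lists), and 3 lists passed without CT913-M1 replicate 2.

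In UWB1.289+BRCA1, IL6 was 11.7-fold higher with CT913-M1 than with CT913 (log2 3.54 ± 0.22), and so were the Notch ligand gene JAG2 (3.23 ± 0.22), IGFBP3 (3.04 ± 0.07), CAPN15 (3.01 ± 0.21) and HMHA1 (2.97 ± 0.23). TP53INP2 (-3.19 ± 0.12), EML6 (-3.16 ± 0.22), BRCA1 (-3.07 ± 0.07), CDKN1A (-3.01 ± 0.14) and NAP1L2 (-2.97 ± 0.26) were lower. GDF15 (1.63 ± 0.12), MGMT (1.61 ± 0.18), DDIT3 (0.43 ± 0.07) and CCNB1 (0.25 ± 0.06) were higher with CT913-M1, and HMOX1 was lower (-0.75 ± 0.19), though not with DESeq2 (-0.74). MDM2 differed by -0.12 ± 0.08, not past the test, but passed without CT913-M1 replicate 1 (-0.21). ATF3 was higher by 0.26 ± 0.11, a call that ended with DESeq2 (0.30), with only the compared groups fitted (0.29), without CT913 replicate 2 (0.18) and without CT913-M1 replicate 1 (0.09). Ribosome biogenesis was higher with CT913-M1 in 29 of 30 cases (30 adjusted over the list alone, median 0.81) and YAP and TEAD targets in 14 of 19 with 2 lower (14 adjusted over the list alone, median 0.63). Both lists passed (adjusted p = 0.0435 and 0.0493 by camera with an estimated correlation), but neither did with RLE scaling, and without CT913 replicate 2 only ribosome biogenesis passed. Without CT913-M1 replicate 1 or 2, 5 lists passed. In all, 9840 genes passed the test, 4750 higher and 5090 lower.

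The lines were also compared in control medium, which for UWB1.289+BRCA1 contained G-418 in addition, per the labels. PASD1, a cancer-testis antigen gene without counts in UWB1.289 control, was at least 209-fold higher in UWB1.289+BRCA1, at 66.5 CPM. MYBPC2 (5.85 ± 0.25), FLT1, which encodes a receptor of VEGF (5.78 ± 0.35), FLRT2 (5.41 ± 0.17), LIX1 (5.19 ± 0.30), MAP1LC3C (5.07 ± 0.27), LRP2 (4.77 ± 0.26) and KCNIP1 (4.73 ± 0.14) were higher too. ARMCX2, COL22A1 and SMOC1 had no counts in UWB1.289+BRCA1 control and were at least 49.8-fold, 41-fold and 28.6-fold lower there, taking 3 counts per library as the floor. CPED1 (-8.22 ± 0.37), the DNA sensor gene IFI16 (-7.48 ± 0.26), the collagen genes COL6A1 (-7.08 ± 0.28) and COL6A2 (-6.51 ± 0.34) and the matrix protease gene MMP2 (-7.07 ± 0.19) were lower as well. Of 7775 genes that passed, 3937 were higher and 3838 lower in UWB1.289+BRCA1. None of the 31 tested lists passed camera with an estimated correlation, against 15 with its preset correlation and 27 by fry. The lowest adjusted p was 0.0739, for NF-kB targets, of which 20 of 25 were lower and none higher (20 adjusted over the list alone, median -1.36). Floors and intervals cover counting error and the spread of these libraries. The lines differ by medium as well as by BRCA1. Other differences that arose while UWB1.289+BRCA1 was derived cannot be told apart from these.

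Whether the response depended on the line was tested as a difference of differences. The values are the change in UWB1.289+BRCA1 minus that in UWB1.289. With CT913 the difference was positive for BRCA1 and for the integrin genes ITGA2 (1.92 ± 0.11), which rose in both lines (2.57 and 0.65 in UWB1.289), ITGA6 (1.32 ± 0.10) and ITGB6 (1.12 ± 0.09), which rose by 0.51 but fell in UWB1.289 (-0.61). It was negative for IGFN1 (-2.38 ± 0.20), SAMD5 (-2.24 ± 0.17) and SYNE2 (-1.24 ± 0.10), which fell in UWB1.289+BRCA1 and rose in UWB1.289, and for IGFBP3 (-1.48 ± 0.10), which fell in both (-3.47, and -2.0 in UWB1.289). In control, ITGA2, ITGA6 and ITGB6 stood lower in UWB1.289+BRCA1 (110, 40.7 and 120 CPM) than in UWB1.289 (355, 241 and 421 CPM). With CT913, ITGA6 and ITGB6 stayed lower there (101 and 170 against 240 and 276 CPM), while ITGA2 reached 655 against 559 CPM. Control levels of IGFN1, SAMD5, SYNE2 and IGFBP3 were higher there (56.9, 58.9, 273 and 545 CPM) than in UWB1.289 (8.07, 7.65, 76.2 and 349 CPM). The difference was positive for 17 of 25 NF-kB targets and negative for none (20 positive adjusted over the list alone, median 1.00), with median changes of 1.45 in UWB1.289+BRCA1 and 0.59 in UWB1.289. For ATF4 targets it was negative in 16 of 34 cases and positive in 1 (20 negative adjusted over the list alone, median -0.39), with median changes of -0.06 and 0.26. Adjusted p was 0.0177 and 0.0213 by camera with an estimated correlation. The number of genes that passed, 1607 (851 higher, 756 lower), was 975 with DESeq2 and fell to 789 and 1054 without UWB1.289 control replicate 1 and 2, 869 and 901 without its CT913 replicates, and 748 and 907 without UWB1.289+BRCA1 control replicate 1 and 2. The NF-kB call ended without UWB1.289+BRCA1 CT913 replicate 2, and the ATF4 call there, without either CT913 replicate of UWB1.289 and without either UWB1.289+BRCA1 control.

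With CT913-M1 the same difference was positive for PTX3 (2.86 ± 0.24) and IL8 (1.31 ± 0.11), which rose in both lines, and for ZFP36L1 (1.14 ± 0.10), which rose in UWB1.289+BRCA1. It was positive also for PCDH19 (1.31 ± 0.10) and the matrix protein gene THBS1 (0.93 ± 0.08), which fell less in UWB1.289+BRCA1 (-0.86 and -0.18) than in UWB1.289 (-2.17 and -1.11). PTX3 started at 1.84 CPM in UWB1.289+BRCA1 control, against 51.9 CPM in UWB1.289 control, and stayed lower with CT913-M1 (35.3 against 132 CPM). IGFN1 (-1.93 ± 0.19), ZNF117 (-1.87 ± 0.14), ERV3-1 (-1.36 ± 0.14) and PHLDB2 (-0.88 ± 0.09) fell in UWB1.289+BRCA1 and rose in UWB1.289, with ZNF117 and ERV3-1 uncertain because the loci share transcripts, and ADAMTS15 (-1.55 ± 0.15) fell in both. The difference was positive for 16 of 25 NF-kB targets (median 1.07), 17 of 27 AP-1 genes (0.83) and 11 of 23 NRF2 genes (0.27), lists with a positive median change in both lines. It was positive for 19 of 36 replication genes (0.41) and 11 of 23 heat shock genes (0.24), whose median falls were smaller in UWB1.289+BRCA1 (-0.53 and -0.33) than in UWB1.289 (-0.83 and -0.66). It was also positive for 16 of 30 ribosome biogenesis genes (0.29; median changes 0.03 in UWB1.289+BRCA1 and -0.17 in UWB1.289) and 9 of 19 YAP targets (0.23; 0.13 and -0.09). It was negative for 1 YAP target and for no member of the other 6 lists, and adjusted over the list alone it was positive for 18, 19, 13, 20, 14, 16 and 9 genes, in the order given. Adjusted p by camera with an estimated correlation was 0.0201 for NF-kB, AP-1 and NRF2, 0.0299 for YAP targets, 0.0343 for replication and ribosome biogenesis and 0.0414 for heat shock. The 3179 genes that passed (1792 higher, 1387 lower) were 1864 with DESeq2, 1823 without UWB1.289 control replicate 2, 2063 without its CT913-M1 replicate 2, and 1812 and 1980 without UWB1.289+BRCA1 control replicate 1 and 2. No list passed without UWB1.289 CT913-M1 replicate 1, while 1 passed without UWB1.289+BRCA1 control replicate 1, and 3 without its control replicate 2 or without UWB1.289 control replicate 1. Without UWB1.289+BRCA1 CT913-M1 replicate 1, 5 lists passed, and heat shock, ribosome biogenesis and YAP targets no longer did.

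The fold changes were compared across all 15784 genes, which are not independent replicates. CT913 gave similar directions in the lines: 2796 genes rose and 2990 fell in both, where independent lists would share 1046 and 1130, 156 were opposite (2176), and r was 0.695. For CT913-M1 the shared numbers were 1488 and 1953 (610 and 753 by independence), with 219 opposite (1356) and r = 0.506. Within UWB1.289, CT913 and CT913-M1 shared 1522 higher and 1912 lower genes (695 and 744 by independence) with r = 0.535, and within UWB1.289+BRCA1 1154 and 1874 (918 and 1143 by independence) with r = 0.335. The 2 compounds changed 399 genes in opposite directions in UWB1.289 (1439 by independence) and 1599 in UWB1.289+BRCA1 (2050), there more than the 1154 that rose with both. Comparisons within a line use the same controls, and groups without any change simulated against them gave r = 0.530 and 0.563, with a covariance of 0.0457 and 0.0723 against 0.227 and 0.223 observed, a difference of 0.181 and 0.151. With each compound against another single control library, r was 0.376 and 0.356 in UWB1.289 (16322 genes), with 804 and 843 genes higher (303 and 336 by independence) and 1220 and 1321 lower (385 and 433) in both, and 192 and 205 opposite (685 and 763). In UWB1.289+BRCA1 r was 0.212 in both arrangements (16357 genes), with 699 and 716 higher (552 and 547) and 1258 and 1289 lower (652 and 653), and 967 and 948 opposite (1200 and 1195). Single controls are noisier, so the drop in r is not a measure of the shared controls alone, and part of the excess with common controls may come from them.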

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

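The tests of scaling for BRCA1, of a UWB1.289 library with CT913 under the other label, of the starting level of NF-kB targets and of immune cells in replicate 1, and the 5 immune markers that were summed, were chosen only after the results were seen. The results below are differences between UWB1.289+BRCA1 and UWB1.289 in the response to a compound, each past a test of that difference itself except the numbers of called genes, whose difference was not tested, with 2 libraries per group.

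The log2 change of BRCA1 with CT913 was higher by 2.80 in UWB1.289+BRCA1 than in UWB1.289. Its change in UWB1.289+BRCA1 was 2.69 at the least over TMM, RLE and no scaling factor, which argues against scaling. In both CT913 libraries 74% of the 100 genes that differ most between the lines lay nearer to the control of the labelled line. That is short of the 90% set before, and the reason was not tested. All 100% differed from the UWB1.289 libraries with CT913 in the direction seen in control. This argues against an exchange of the lines under CT913 and does not bear on other wrong labels. Libraries labelled UWB1.289 held BRCA1 at or under 26 CPM, so such a library under the other label would not give this rise. For the cell's own promoter, NBR2 had an upper 95% bound of 0.295 in UWB1.289+BRCA1, which met the bound set before. NBR2 rose by 0.70 in UWB1.289 without BRCA1, so it does not track BRCA1 and cannot decide. BRCA1 itself changed by -0.11 with CT913 in UWB1.289 (95% interval -0.33 to 0.11). This argues against a response of the cell's own promoter that both lines share, and a response in UWB1.289+BRCA1 alone stays open. A candidate explanation, untested here, is that the promoter driving the added copy responds to CT913, and G-418 in the medium of this line is confounded with it.

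The log2 change of NF-kB targets with CT913-M1 was higher in UWB1.289+BRCA1, by a list median of 1.07. With RLE the list median was 1.09 and with thinned libraries 1.12, so it did not rest on the choice of TMM. Thinning leaves the expected ratio of counts unchanged, so it could not decide on depth. RLE like TMM assumes that most genes do not change, so an error shared by both is not excluded. PTPRC, CD3E, CD3D, MS4A1 and CD14 summed to 16.4 and 10.1 CPM in the CT913-M1 libraries of UWB1.289+BRCA1 and to 3.49 to 7.51 CPM in the 10 others, with CD3E at 0.867 and CD3D at 0.124 CPM in replicate 1 (at most 0.136 and 0 in any other library) beside LYZ at or under 0.0943 and NKG7 at or under 0.136 CPM in all. The CD3E and CD3D levels rest on few reads. A few lymphocytes in replicate 1 may be present and cannot be told apart from expression by the line, but without replicate 1 the list median was 1.04 (SE 0.202), which argues against cells in that library as the whole source. With CT913-M1 the targets in UWB1.289+BRCA1 lay at a median of -0.279 (SE 0.246) against UWB1.289 control, from -1.36 in control. A lower starting level in UWB1.289+BRCA1 may therefore account for the larger rise. The call of this list ended without UWB1.289 CT913-M1 replicate 1. BRCA1 status, G-418 and any other difference from the derivation of UWB1.289+BRCA1 differ together between the lines.

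More genes were called with CT913-M1 in UWB1.289+BRCA1 (8009) than in UWB1.289 (5359, or 3219 without control replicate 1 and 3315 without CT913-M1 replicate 1), and 3179 genes differed between the lines in this response. With all libraries thinned to 7336579 counts the ratio was 1.53 (7304 and 4771 genes), which argues against depth. The SD of the log2 changes was 1.43 times as large in UWB1.289+BRCA1 (0.541 against 0.378 over 10008 genes). This SD also holds replicate noise, so it cannot decide on a smaller spread between replicates. The model shared its estimate of spread over all groups, so a smaller spread in 1 line would not by itself give that line more calls. Chi-square per degree of freedom between replicates was 5.91 in UWB1.289+BRCA1 and 2.44 in UWB1.289 with CT913-M1, and 1.24 and 1.54 in control. Larger changes over many genes in UWB1.289+BRCA1 at this dose may explain the excess, as a hypothesis from the same data, although replication and heat shock genes fell less there. Leaving out 1 library moved the number of genes past the test of this difference, counted anew in each fit rather than among the 3179.

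With CT913, 1607 genes differed between the lines in their response, or 748 without UWB1.289+BRCA1 control replicate 1, 907 without its replicate 2, 789 and 1054 without UWB1.289 control replicate 1 and 2, and 869 and 901 without UWB1.289 CT913 replicate 1 and 2. The change in UWB1.289+BRCA1 minus that in UWB1.289 was positive for the adhesion genes ITGA2 (1.92), ITGA6 (1.32) and ITGB6 (1.12), for CCNB1 (0.30), which fell less, and for the NF-kB list (median 1.00, not called without UWB1.289+BRCA1 CT913 replicate 2). It was negative for IGFN1 (-2.38), SAMD5 (-2.24), SYNE2 (-1.24) and IGFBP3 (-1.48), for GDF15 (-1.42) and DDIT3 (-0.57), which rose less, and for the ATF4 list (median -0.39), whose call ended without UWB1.289+BRCA1 CT913 replicate 2, either UWB1.289 CT913 replicate or either UWB1.289+BRCA1 control. Of 59 genes named for CT913, mostly picked for their changes against control, 29 passed this test, 17 with a positive and 12 with a negative difference, against 10.2% of all 15784 genes (851 positive, 756 negative). In control, ITGA2, ITGA6 and ITGB6 were lower in UWB1.289+BRCA1 than in UWB1.289, and IGFN1, SAMD5, SYNE2 and IGFBP3 were higher. GDF15 and DDIT3 were higher there too, in control (18.3 and 70 against 4.54 and 30.6 CPM) and with CT913 (45.4 and 87 against 29.9 and 56.7 CPM). How far starting levels account for these differences was not tested.

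With CT913-M1 this difference was positive for PTX3 (2.86, from a control level of 1.84 CPM in UWB1.289+BRCA1), IL8 (1.31), ZFP36L1 (1.14) and ATF3 (1.09). It was positive also for PCDH19 (1.31) and THBS1 (0.93), which fell less in UWB1.289+BRCA1. It was negative for IGFN1 (-1.93), ZNF117 (-1.87), ADAMTS15 (-1.55), ERV3-1 (-1.36) and PHLDB2 (-0.88), and for DDIT3 (-0.70), which rose less. Its median was positive for the AP-1 (0.83), NRF2 (0.27), ribosome biogenesis (0.29) and YAP (0.23) lists, and for replication (0.41) and heat shock (0.24), which fell less, none of which was called without UWB1.289 CT913-M1 replicate 1. Heat shock, ribosome biogenesis and YAP targets were not called without UWB1.289+BRCA1 CT913-M1 replicate 1. Without UWB1.289+BRCA1 control replicate 1 there was 1 list, and 3 without its replicate 2 or without UWB1.289 control replicate 1. Of 59 genes named for CT913-M1, picked in the same way, 41 passed this test, 31 with a positive and 10 with a negative difference, against 20.1% of all genes (1792 positive, 1387 negative). DDIT3 was higher in UWB1.289+BRCA1 than in UWB1.289 in control (70 against 30.6 CPM) and with CT913-M1 (117 against 83 CPM).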

How the results depend on the processing

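Leaving out single libraries for lists and separate controls for correlations were chosen only after the data were seen; the other alternatives were not. A library left alone in its group is assumed to vary like the other groups. Over 229 results for named genes and their alternatives, 1884 values kept direction and side of the threshold, 11 kept direction but no longer passed, 1 newly passed and 12 changed sign. For the 43 called lists, 238 values stayed past the threshold and 99 kept their direction without passing. All 43 passed with the preset correlation and by fry, which both called more lists in every comparison, and 33 passed with RLE.

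Counts of called genes stayed within 1.5 times in all comparisons with RLE, without a filter and with the compared groups alone. DESeq2 called 3454 instead of 5359 genes for CT913-M1 in UWB1.289, 975 instead of 1607 for the difference between lines with CT913, and 1864 instead of 3179 for that with CT913-M1; the cause was not tested. Leaving out 1 library gave 3219 to 4074, 748 to 2290 and 1812 to 3995 genes for these 3, with fewer samples to fit. For CT913-M1 in UWB1.289, control replicate 1 (3219) and CT913-M1 replicate 1 (3315) moved the count by over 1.5 times.

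All 12 sign changes were in values not past the test in either setting. MDM2 with CT913-M1 in UWB1.289+BRCA1 (-0.01) was 0.00361 with RLE, 0.0678 without a filter, 0.0138 with DESeq2, 0.0456 with the compared groups alone, and -0.0983 to 0.0914 with a library left out. Between CT913-M1 and CT913 in UWB1.289, MDM2 (-0.02) was 0.0119 without a filter and -0.0467 to 0.00847 with a library left out, and the ranges were -0.0971 to 0.0307 for BRCA1 (-0.03) and -0.0125 to 0.248 for GDF15 (0.12). The cause was not tested.

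The number of called lists rose with the preset correlation and with fry, and the cause was not tested. For CT913 in UWB1.289 it was 6, against 22 (preset) and 29 (fry), with 0 to 1 when a library was left out. For CT913-M1 in UWB1.289 it was 7, against 15 and 19, with 3 to 7. For CT913 in UWB1.289+BRCA1 it was 13, against 21 and 28, and 8 with RLE, with 5 to 11. For CT913-M1 in UWB1.289+BRCA1 it was 5, against 18 and 26, with 5 to 8. Between the compounds it was 1, against 21 and 27, with 0 to 3, in UWB1.289, and 2, against 13 and 28, and 0 with RLE, with 1 to 5, in UWB1.289+BRCA1. Between the lines it was 0, against 15 and 27. For the differences between lines it was 2, against 12 and 17, with 0 to 2 (CT913), and 7, against 14 and 18, with 0 to 9 (CT913-M1). The effect of RLE and of single libraries on lists near the threshold had no cause tested.

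The correlation of changes between CT913 and CT913-M1 was 0.433 to 0.616 in UWB1.289 and 0.271 to 0.463 in UWB1.289+BRCA1 when a library was left out, and 0.242 in the latter over genes of at least 10 CPM. With a separate control for each compound it was 0.376 and 0.356 in UWB1.289 and 0.212 in both arrangements in UWB1.289+BRCA1. Between the lines it was 0.600 to 0.647 for CT913 and 0.350 to 0.453 for CT913-M1, and 0.809 and 0.651 over genes of at least 10 CPM, where noise of low counts is smaller. The share of called genes that were higher moved by more than 10 points with DESeq2 for the difference between lines with CT913 (53 to 65.5%) and CT913-M1 (56.4 to 68.4%), and without a filter for CT913-M1 in UWB1.289+BRCA1 (46.6 to 58.4%) and its difference between lines (69.4%). On data simulated at these depths and numbers of libraries, 46.2% of 65 genes changed by 0.5 were recovered. Far fewer genes were changed there than were called here, so recovery in the real comparisons may differ. Depth alone was not varied.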

Other observations

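No test in this part was chosen after the results were seen, but the genes named here lie outside the rule for named genes and were picked after their values were seen. Metallothionein genes, which encode metal-binding proteins, rose with CT913-M1 in UWB1.289+BRCA1 in 8 of 9 list members with 1 lower (8 adjusted over the list alone, median 1.80), with MT2A at 2.53 ± 0.14 and MT1X at 2.69 ± 0.16, but the list did not pass (adjusted p = 0.146 by camera with an estimated correlation). With CT913 in the same line MT2A rose by 0.68 ± 0.14 and MT1X changed by -0.27 ± 0.21, not past the test. Values of single metallothionein genes are uncertain, since shared reads between near-identical copies were not measured. All 35 ribosomal protein genes fell with CT913 in UWB1.289+BRCA1 (35 adjusted over the list alone, median -0.56), among them RPL5 (-0.64 ± 0.05) and RPL3 (-0.68 ± 0.06), at an adjusted p of 0.094 by camera with an estimated correlation.

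The other lists that passed in none of the 9 comparisons follow with the comparison of lowest adjusted p, by camera with an estimated correlation. With CT913 in UWB1.289+BRCA1, Fanconi anemia genes fell in 10 of 19 cases and rose in 2 (median -0.35, 0.0603), base excision and direct reversal genes fell in 14 of 22 and rose in 1 (-0.44, 0.094), and ovarian lineage genes fell in 6 of 9 (-0.66, 0.0934). With CT913 in UWB1.289, keratin genes fell in 5 of 9 (-0.56, 0.0763). With CT913-M1 in UWB1.289+BRCA1, unfolded protein response genes rose in 10 of 24 and fell in 1 (0.12, 0.146) and epithelial genes rose in 12 of 20 and fell in 2 (0.36, 0.263). Against UWB1.289 control, UWB1.289+BRCA1 control had 24 of 29 interferon genes lower and 1 higher (-1.68, 0.11) and 10 of 15 mesenchymal genes lower and 1 higher (-1.23, 0.11). The change with CT913-M1 in UWB1.289+BRCA1 minus that in UWB1.289 was positive for 3 of 11 AhR genes (0.37, 0.191) and for 9 of 20 TGF-beta targets and negative for 1 (0.46, 0.122), and 4 of 8 histone genes were lower with CT913-M1 than with CT913 in UWB1.289 (-0.66, 0.236). Adjusted over the list alone these counts were the same except 13 epithelial genes higher, 11 mesenchymal genes lower, and 10 TGF-beta targets positive and 2 negative. Median and mean differed in sign for several lists that were not called, among them ATF4 targets (-0.06 and 0.02) and hypoxia genes (-0.01 and 0.13) with CT913, and for PPAR targets (-0.12 and 0.25) with CT913-M1, all in UWB1.289+BRCA1, where camera leaned down, down and up.

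Markers of other cell types had 3 measured genes per list and were not tested as lists, and the 13 mitochondrially encoded genes had no counts. Of the fibroblast markers, COL1A2 fell with CT913 and CT913-M1 in UWB1.289 (-1.54 and -1.71) and in UWB1.289+BRCA1 (-2.63 and -1.74), THY1 fell in UWB1.289 (-1.99 and -1.19), and COL1A1 rose with CT913 in UWB1.289, to 4.15 and 4.63 CPM from at most 1.83 in control. CD68, a lysosomal marker of macrophages, rose by 1.85 and 1.06 in UWB1.289 and by 2.61 and 1.76 in UWB1.289+BRCA1, while CD14 fell with CT913 in UWB1.289 (-1.88) and PTPRC changed by -0.61 there, not past the test, and rose with CT913-M1 in UWB1.289+BRCA1 (0.84). The fall of CD14 rests on few reads, from 0.796 and 1.08 CPM in control to 0.283 and 0.273 CPM. CDH5, an endothelial cadherin gene, was lower in UWB1.289+BRCA1 control than in UWB1.289 control (-3.93), and fell with CT913 in UWB1.289 and UWB1.289+BRCA1 (-0.95 and -1.09), while KDR (-1.55) and VWF (-1.35) fell with it in UWB1.289. VWF also rests on few reads, at 1.19 and 2.37 CPM in UWB1.289 control and 0.566 and 1.09 CPM with CT913.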
